A study of Verbena bonariensis with 2 samples.

How the data were processed

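Gene expression was measured by RNA sequencing in leaves of Verbena bonariensis, an ornamental perennial, cultivar Finesse, from plants about a month old. The libraries were made from total RNA by Illumina methods, per the labels' protocols. The labels put 1 library in the untreated group and 1 library in the cadmium group, which received 350 µmol/L cadmium. The series description also speaks of 2 kinds of leaves without saying what the kinds are. Both labels name leaves of the same cultivar, so whether the libraries differed in anything besides cadmium is not known, and any such difference would enter every ratio. The length and route of the treatment, and whether a library pooled several plants, are not given in the sources used here.

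Each library came as a table of 63021 clusters with an estimated count and an FPKM value (fragments per kilobase of cluster, scaled to library size). The estimated counts, as deposited, carry 2 decimals and are not normalized: 44.3% of the untreated and 43.6% of the cadmium values differed from a whole number by more than 0.005. The deposited FPKM values were normalized by the authors for cluster length and library total, per the file headers and the values. The submitters' processing notes list Bowtie2 2.0.6 and TopHat2 2.0.9 with no role. The assembler, the counting tool and the reference sequence are not given in the sources used here. The length behind an FPKM value was recovered as the count divided by FPKM and by the library total. This effective length agreed within 5% between the libraries for 99.9% of the 37702 clusters with an FPKM of at least 1 in both. Estimated counts divide reads that fit several similar sequences, so values of near-identical clusters are uncertain. The protocol in the labels does not say whether the libraries kept strand.

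The identifiers have the form Cluster-x.y. The first number was read as a component of related sequences and the second as its member, which no source used here states. So read, the clusters fell into 14189 components. The largest, component 7663, held 45612 clusters (72.4%) with 97.9% of the untreated and 98.0% of the cadmium counts. A further 12112 components were single clusters, and 2076 had between 2 and 12. The files do not pair clusters with gene names, and no genome or annotation was used here. Lists of metal-transport, glutathione, antioxidant, chaperone, photosynthesis, chlorophyll, phenylpropanoid, cell-wall, hormone, transcription-factor, ribosomal and marker genes that had been fixed before the data were examined were therefore not evaluated, and clusters are described by abundance, length and component.

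Estimated counts were rounded to whole numbers. Library sizes were scaled by the trimmed mean of M-values (TMM) in edgeR 4.0.16 under R 4.3.3, with factors of 1.02 for the untreated and 0.978 for the cadmium library. Clusters with at least 1 CPM (counts as a share of the library total, in parts per 1000000) in at least 1 library were kept, which left 36565. The ratio of cadmium to untreated counts was given with an exact (Clopper-Pearson, conditional binomial) 95% interval in scipy 1.17.1. A cluster was called higher or lower by a fixed rule of size, when this interval lay wholly above 2 or wholly below 0.5. Log2 ratios for display carry a pseudocount of 1 count scaled to library size. With 1 library per group there are no residual degrees of freedom, so edgeR's quasi-likelihood test could not be fitted and no p-value is given. Intervals of ratios and of shares of reads cover counting error only, intervals of shares of clusters treat clusters as independent, and every comparison is between these 2 libraries, not between replicated conditions. Reads were not described as carrying molecular identifiers, so they are not independent molecules. For a cluster at 0 the fold is a lower bound, computed against a floor of 3 counts per library (0.172 CPM in the untreated and 0.182 CPM in the cadmium library). This floor is a one-sided limit, so the end of the exact two-sided interval used for the calls is a smaller fold. Neither covers reads assigned to another, similar cluster.

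The rule of size was tested on simulated data for the untreated against cadmium comparison, drawn from the real clusters' means and library sizes with 200 changed clusters. The changed clusters were picked among those with a mean of at least 5 CPM, so recovery at lower abundance was not measured. With Poisson error alone the rule recovered 96.0% of 50 clusters changed by 3-fold and all 50 changed by 8-fold, and called 1 of 34899 unchanged clusters. With an assumed coefficient of variation between plants of 0.2 it called 105 of 35062 unchanged clusters, and with 0.4 it called 2832 of 35346. Recovery of the 3-fold changes was 80% at 0.2 and 80% at 0.4. The clusters named by identifier were fixed by a rule before the data were examined: those 2 with the largest and those 2 with the smallest TMM-scaled log2 ratio among called clusters with at least 10 CPM in at least 1 library. Alternatives covered the scaling (library totals, DESeq2 1.42.0 size factors, FPKM ratios), the filter, the pseudocount, the rule of size, an assumed spread between plants, thinning, a length minimum and 1 cluster per component. Figures were drawn in matplotlib 3.10.9.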

Results

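The transcriptome of leaves was compared between untreated Verbena bonariensis plants and plants treated with 350 µmol/L cadmium, a toxic heavy metal. The aim was to find transcripts whose abundance differed with cadmium. Each condition was represented by 1 library, both labelled with the same cultivar. The untreated library held 17455521 and the cadmium library 16476612 estimated counts over 63021 assembled transcript clusters. Counts above 0 were listed for 56833 clusters in the untreated and 55880 in the cadmium library, and 3152 clusters were at 0 in both. At least 1 CPM was reached by 33761 clusters in the untreated and 33090 in the cadmium library. The median count per cluster over all clusters was 21.9 and 19.1, and clusters that reached 1 CPM in a library had a median mean abundance of 5.01 CPM. There were no replicates. Intervals of ratios and of shares of reads cover counting error only, and intervals of shares of clusters are binomial over clusters taken as independent.

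The abundance profiles of the libraries were alike for most clusters. Across clusters, which are not independent replicates, log2(CPM + 1) had a Pearson r of 0.964 and a Spearman rho of 0.893. Of the 36565 clusters with at least 1 CPM in a library, 30282 (82.8%) had a fitted ratio within 2-fold, with quartiles of the log2 ratio at -0.36 and 0.36. In all, 11.2% of reads would have to move between clusters to turn one profile into the other. Counting error alone contributes to this share, and its part was not estimated. The most abundant 10 clusters took 6.89% of counts in the untreated library (exact binomial 95% interval 6.88 to 6.91) and 7.51% in the cadmium library (7.49 to 7.52). These lists of 10 shared 6 clusters, and the lists of the top 100 shared 90. The top 100 held 22.6% (22.57 to 22.61) and 24.5% (24.48 to 24.52) of counts. The slightly greater weight of abundant clusters in the cadmium library exceeded counting error, and its spread between plants is unknown.

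Similar numbers of clusters were higher and lower with cadmium, and these sets held similar shares of the untreated counts. With cadmium, 1472 clusters (4.03%, 3.83 to 4.23) were higher and 1407 (3.85%, 3.65 to 4.05) were lower by the rule of size. The higher clusters together made up 1.71% of untreated and 5.45% of cadmium counts, 3.33-fold higher in cadmium after TMM scaling (3.32 to 3.34). Among them, 9 clusters with a mean over 1000 CPM held 2.69% of cadmium counts. The lower clusters made up 1.62% of untreated and 0.401% of cadmium counts, which was 3.87-fold lower in cadmium (3.84 to 3.91). The higher and lower clusters were chosen for their ratios, so the summed folds and the unequal cadmium shares describe them and are not independent evidence of a change. Simulated libraries with no effect in most clusters yielded 105 calls among unchanged clusters at an assumed coefficient of variation between plants of 0.2 and 2832 at 0.4. How many simulated calls lay at 0 in a library was not counted, whereas 48.9% of the real calls did. With a spread of 0.4 built into the interval, 646 higher and 667 lower clusters were still called. For a cluster at 0 in a library, this widening shifts the bound by a constant factor. Such clusters with enough counts in the other library therefore stay called by construction, and their share of these calls is not given. The simulation does not give the share of real calls owed to spread between plants, which is unknown. The total of 2879 calls can therefore not be read as a number of cadmium-responsive genes.

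**Figure D1:**
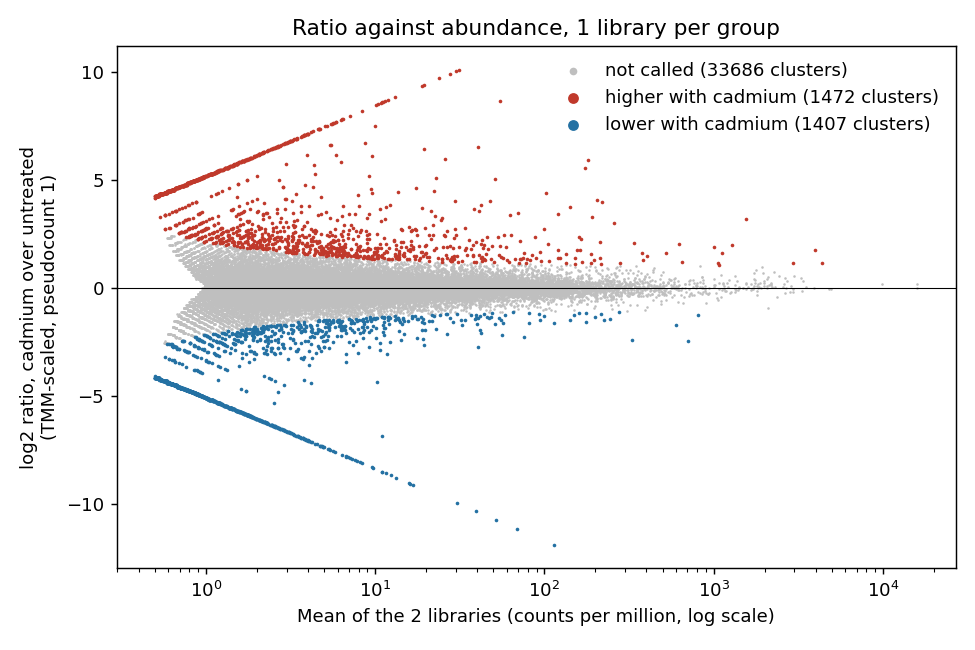
Each point is 1 of 36565 clusters; the horizontal axis gives the mean of the libraries in CPM on a log scale and the vertical axis the TMM-scaled log2 ratio of cadmium over untreated with a pseudocount of 1. Red points are the 1472 higher and blue points the 1407 lower clusters, and the outer diagonal lines of points are clusters with 0 counts in a library.

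Among the few abundant clusters that were called, more were higher than lower with cadmium. The median log2 ratio after scaling was 0.0037 over the 11151 clusters at 10 to 100 CPM and -0.0053 over the 1467 at 100 to 1000 CPM. Over the 107 clusters above 1000 CPM the median was 0.082. All 9 called clusters with a mean over 1000 CPM, of 107 such clusters, were higher with cadmium, with ratios from 2.09 to 9.21; with library totals 8 were higher. These 9 clusters took 0.986% of untreated counts (0.982 to 0.991) and 2.69% of cadmium counts (2.68 to 2.69). At 100 to 1000 CPM, 37 clusters were higher and 16 lower, and at 10 to 100 CPM 214 were higher and 110 lower. At 1 to 10 CPM the numbers were close, with 778 higher and 727 lower. Among calls at 10 CPM or more, 67.4% were higher (exact binomial 95% interval 62.4 to 72.0). The excess of higher calls at 10 CPM or more kept its direction with library totals, where 233 were higher and 148 lower, and with DESeq2 size factors, where 258 were higher and 130 lower. At 1 to 10 CPM the direction depended on the scaling, since library totals gave 732 higher and 783 lower. Clusters with a mean under 1 CPM passed the filter through 1 library alone, so their 434 higher and 554 lower calls are partly set by the filter.

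**Figure D2:**
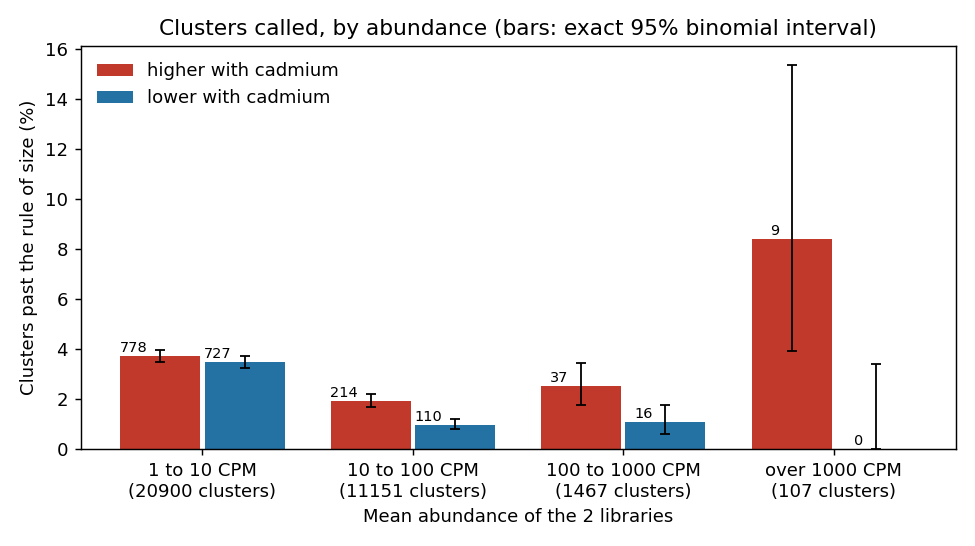
Bars give the percentage of clusters called higher (red) or lower (blue) with cadmium in each class of mean abundance from 1 CPM up. Exact 95% binomial intervals and the number of calls are shown for each bar. The class under 1 CPM (434 higher and 554 lower of 2940 clusters) is not drawn. Higher and lower calls are close in number at 1 to 10 CPM (778 and 727), and over 1000 CPM there are 9 higher and 0 lower, where the interval for 0 of 107 reaches 3.39%.

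The balance of large differences depended on which clusters were tallied and by which rule, and clusters at 0 changed the size of the excess. Over all 36565 clusters passing the filter, the interval lay wholly beyond 4-fold for 790 higher and 867 lower clusters. Among clusters with at least 100 counts in the higher library, judged by the ratio itself and not its interval, 248 were more than 4-fold higher and 160 more than 4-fold lower. Of the same clusters, 123 were more than 10-fold higher and 88 more than 10-fold lower, so that 58.3% were higher (exact binomial 95% interval 51.3 to 65.0). Beyond 20-fold, 93 were higher and 83 lower (52.8%, 45.2 to 60.4), an interval that includes equal numbers. These tallies at 100 counts, added after seeing the data, take clusters at 0 at their bound against the floor of 3 counts. By that bound all such clusters, 60 higher and 76 lower, pass each of these folds by construction. With counts above 0 in both libraries, a restriction that itself depends on the size of the difference, 63 were more than 10-fold higher and 12 more than 10-fold lower, of which 3 in each direction had an estimated count that rounds to 0 in the other library. The 63 clusters had median abundances of 0.859 CPM in the untreated and 18.3 CPM in the cadmium library. The 12 clusters had medians of 7.67 CPM in the untreated and 0.426 CPM in the cadmium library. Library totals gave 121 higher and 89 lower beyond 10-fold with clusters at 0 included, and DESeq2 size factors gave 123 and 88.

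Many of the strongest differences were clusters with counts in a single library. With at least 10 counts in one library and 0 in the other, 1399 clusters were seen in the untreated library only and 974 in the cadmium library only. Their median counts were 21.0 and 19.0, and they held 0.338% of untreated and 0.226% of cadmium counts. They formed 827 of the 1407 lower and 580 of the 1472 higher calls; every one of them that passed the filter met the rule of size, which the filter and the rule ensure. Without any cluster at 0 in a library, an alternative added after seeing the data, 892 clusters were higher and 580 lower. Among clusters with at least 100 counts in the untreated library, 76 were at exactly 0 in the cadmium library, while 12 lay above 0 and below a ratio of 0.1. In the reverse direction 60 clusters were at exactly 0 and 63 lay above 0 and below 0.1. By counting error, a count of 0 allows up to 3 counts, and the fold of these clusters is known only as a lower bound. Estimated counts divide reads among similar sequences, so a 0 can also arise when reads are assigned to another cluster. The bound does not cover that case.

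**Figure D3:**
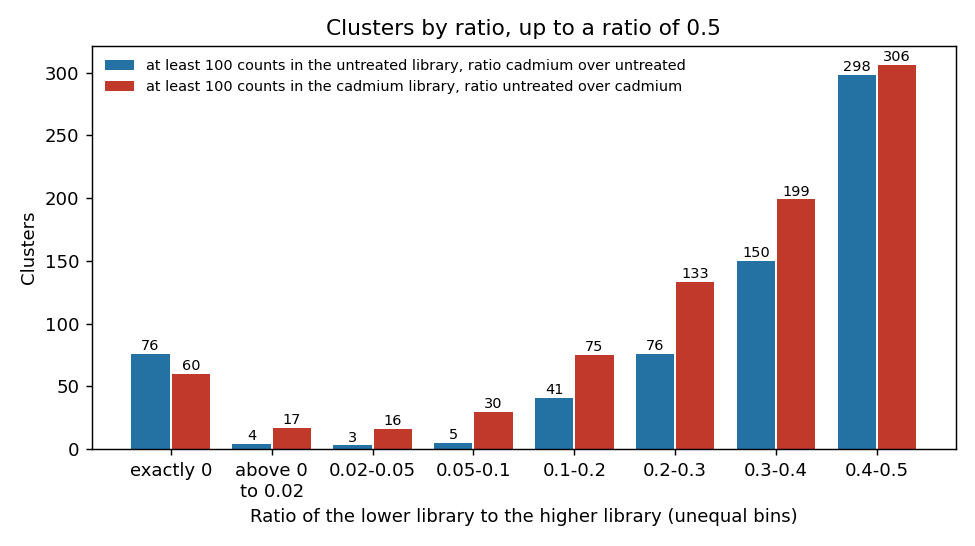
Bars count clusters with at least 100 counts in the untreated library (blue) or in the cadmium library (red) by the TMM-scaled ratio of the other library to it, in unequal bins up to a ratio of 0.5. In blue, 76 clusters sit at exactly 0 and 4, 3 and 5 in the next bins; in red, 60 sit at 0 and 17, 16 and 30 in the next bins.

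The clusters with the most extreme fitted log2 ratios in each direction were all of this kind, an order that rests on the pseudocount of 1, since their folds are bounds. Cluster-7663.3078 had 1037 counts (62.9 CPM, FPKM 152 as deposited) in the cadmium library and 0 in the untreated library, at least 383-fold higher with cadmium against the floor of 3 counts, while the exact 95% interval of the ratio starts at 311-fold. Cluster-291.2, in a component of 3 clusters, had 994 counts (60.3 CPM) with cadmium and 0 without, at least 367-fold higher against the floor, with an interval from 298-fold. Cluster-7663.17046 had 3981 counts (228 CPM) in the untreated library and 0 in the cadmium library, at least 1199-fold lower against the floor, with an interval from 975-fold. Its effective length was 46.2 bases, and its deposited FPKM of 4939 ranked 10 in the untreated library while its count ranked 582. Cluster-8788.0, in a component of 5 clusters and with an effective length of 2643 bases, had 2398 counts (137 CPM) in the untreated library and 0 with cadmium, at least 722-fold lower against the floor, with an interval from 587-fold. These bounds cover counting error only, not reads assigned to another cluster. Cluster-7663.3078 and Cluster-7663.17046 lie in the largest component, where such reassignment could not be excluded. Which genes the named clusters represent is not known, because the files do not pair identifiers with names.

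Clusters outside the largest component were called more often than those within it. In the largest component 1003 of 30443 clusters (3.29%, 3.10 to 3.50) were higher and 859 (2.82%, 2.64 to 3.01) lower. In components of 2 to 12 clusters, 157 of 2253 (6.97%, 5.95 to 8.10) were higher and 134 (5.95%, 5.01 to 7.01) lower. Of the 3869 single clusters, 312 (8.06%, 7.23 to 8.97) were higher and 414 (10.7%, 9.74 to 11.7) lower. The single clusters were less abundant, with a median of 1.63 CPM against 6.80 CPM in the largest component. Within clusters of 1 to 10 CPM, 10.1% outside the largest component were called against 6.37% within it, although their median abundance was also lower (2.06 against 3.24 CPM). By effective length, clusters under 300 bases had 93 higher and 144 lower calls of 2787, and clusters over 2000 bases had 327 and 366 of 8044. Clusters of 300 to 1000 bases had 509 higher and 456 lower of 12332, and those of 1000 to 2000 bases 543 and 441 of 13402.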

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

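No paired analysis was possible because each group has 1 library, and no replicate could be left out; the limits of all counts are the counting depth and the unknown spread between plants. Of 38 values of the numbers of higher and lower clusters under alternatives, 20 stayed within 1.5 times the reported 1472 and 1407, including library totals (1391 and 1499), DESeq2 size factors (1465 and 1421), FPKM ratios (1393 and 1499) and thinning to equal totals (1463 and 1408). Higher and lower counts that moved further were 605 and 379 with at least 5 CPM (61.5% higher, against 51.1%), 3135 and 3148 with a 2-fold point estimate and no interval, 3210 and 3209 for that with a pseudocount of 0.5, 2679 and 2662 with a pseudocount of 5, 790 and 867 with the interval beyond 4-fold, 646 and 667 with an assumed coefficient of variation of 0.4, and 385 and 483 with 1 cluster per component. The last setting keeps 1 of the 45612 clusters of the largest component, so it tallies almost only the other components. Alternatives added after seeing the data gave 892 and 580 without clusters at 0 in a library and 466 and 481 with whole counts only. These counts fell or grew by construction, as fewer or more clusters could pass. Clusters in the untreated or the cadmium library only numbered 2188 and 1578 from 5 counts, 741 and 465 from 20 counts, and 3719 and 2817 with FPKM above 0.3 against 0. Summing the clusters of each component outside the largest gave 691 and 428 (added after seeing the data). This leaves out the 590 and 438 such clusters of the largest component. Before summing, components of 2 to 12 held 179 such clusters in the untreated and 145 in the cadmium library, and 630 and 391 were single clusters. By FPKM, the top 10, 100 and 1000 clusters held 10.6%, 25.7% and 51.9% in the untreated library and 11.5%, 27.5% and 53.3% in the cadmium library; by counts the top 1000 held 49.8% and 51.2%. The correlations across clusters were 0.882 (Pearson) and 0.785 (Spearman) with FPKM and 0.919 and 0.915 with at least 5 CPM; the cause was not tested. The 4 named clusters are at 0 in a library, so no scaling or pseudocount could turn their direction; 7 of 20 values of their log2 ratio left the exact interval, as for Cluster-8788.0, which moved from -11.16 to -5.73 with FPKM plus 1. The gene lists were not run under any alternative.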

Other observations

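All tests in this part were chosen after the values they concern had been seen, except that on reassignment within the largest component. Log2 ratios of clusters of the same component were positively correlated, more weakly once clusters at 0 in a library were left out. In 663 components of 2 to 12 clusters with at least 2 members passing the filter, the log2 ratios of the pair of members with the most untreated counts had a Pearson r of 0.427 and a Spearman rho of 0.232 across components, which are not replicates. The highest Pearson r of 1000 shuffles of the members was 0.148. With clusters at 0 in a library left out, 594 components gave a Pearson r of 0.226 and a Spearman rho of 0.177. No shuffled value is given for that set. Estimated counts divide reads among similar sequences, so values of related clusters are not independent measurements. At least 1 member was called in 152 of the 663 components. In 20 of them at least 2 members were higher, in 20 at least 2 were lower, and in 11 members were called in both directions.

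Clusters with an effective length under 50 bases numbered 3178 and held 0.127% of untreated and 0.113% of cadmium counts, but 6.10% and 5.59% of the FPKM total. Rankings of single clusters by FPKM therefore differ from rankings by counts. Of the 3152 clusters at 0 in both libraries, 75.5% were in the largest component, close to its 72.4% share of all clusters.

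The pattern most worth following up is the 2373 clusters with counts in a single library, most of them with few counts. Whether they form a class apart from graded differences was not tested; with at least 100 counts in the untreated library 76 clusters were at 0 and 4, 3 and 5 in the next bins of the ratio (to 0.02, 0.05 and 0.1), and with at least 100 in the cadmium library 60 were at 0 and 17, 16 and 30 in those bins. Whether reads were reassigned to sibling clusters, in components of 2 to 12, could not be decided. There 25.3% of 324 such clusters (20.7 to 30.4) had a sibling that gained at least 50% of the missing reads. This criterion misses reads spread over several siblings or moved outside the component. No share among other clusters was available for comparison there. In the largest component reassignment cannot be told apart either. A large enough gain existed for 100% of its 1028 such clusters and for nearly all uncalled ones. Sequences of other plants or organisms present in one library may also give such clusters: 56.7% of them lay outside the largest component, 22.5 percentage points (20.6 to 24.6) more than the 34.1% of clusters matched on count, but a gene switched on or off could lie there too and no sequences were used here, so these cannot be told apart. A response to cadmium stays open as a biological explanation and was not tested, since group and library coincide.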
